A study of Mus musculus with 8 samples.

How the data were processed

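The data were 8 lists of CUT&RUN peaks from mouse embryonic stem cells. In CUT&RUN an antibody directs micrococcal nuclease to the chromatin sites of a protein, and the DNA fragments cut free are sequenced. Per the labels, an antibody against METTL14 was used in cells labelled Mettl3 control and Mettl3 CKO, and METTL3 was profiled in cells labelled Mettl14 control and Mettl14 CKO, with 2 libraries per group. The labels do not spell out CKO or say how the cells were made. They do not say that the libraries of a group came from separate cultures, so p-values over libraries measure the spread between these libraries only, which may be technical. Antibody and cell line changed together, so the antibodies were compared within the control lines only as different antibodies in different lines. No library made with a nonspecific antibody, or with an antibody in cells lacking its own target, was analysed here.

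The submitters' processing notes name CASAVA, Trimmomatic 0.38, Bowtie2 2.4.1, SAMtools and HOMER, with no role or order, and the mm10 build. The peak threshold, any background library used in calling and the depth of each library are not given in the sources used here. Each library had its own deposited list, so replicates were not pooled. Each deposited list gives the start and end of every peak in mm10 coordinates, and a score. The deposited score was 1 for every peak in all 8 lists, and the lists hold no height, fold enrichment or p-value. Within a METTL14 list the peaks were 149 bp wide, apart from 1 peak in each of 2 lists. The METTL3 lists had peaks of 285 and 277 bp in the controls and 267 and 245 bp in the CKO libraries. A list therefore shows where signal passed the authors' threshold, and the number of peaks depends on a read depth that is unknown. Intervals given for shares are 95% Wilson intervals and cover counting error only.

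Peaks were counted as overlapping when they shared at least 1 bp. A replicated region was a merged region touched by a peak of both libraries of a group. The share of replicated control regions overlapped by a replicated CKO region was set against 10000 circular shifts of the regions within each chromosome (one-sided, smallest possible p 0.0001). That test is over positions and says nothing about the spread between libraries. Peak numbers were compared on the log2 scale with an exact permutation test of the 4 labels of an antibody (two-sided, smallest possible p 0.33). Jaccard indices, the bases shared by 2 lists divided by the bases covered by either, were compared within and between groups over the 3 splits of 4 libraries into pairs (exact permutation, smallest possible p 0.33).

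Genes came from the RefSeq table for GRCm38.p6, the assembly behind mm10, with 21900 protein-coding genes. The table used here gives gene starts and ends but no strand, exons or UTRs. The planned promoter, 2 kb around a transcription start, was replaced by 2 kb around either boundary of a protein-coding gene, which includes gene ends. Whether a peak inside a gene was exonic or intronic was not analysed here. Shares at boundaries were tested against 10000 circular shifts (two-sided, smallest possible p 0.0002). Before the data were examined, 18 gene lists were fixed. They covered pluripotency factors, developmental transcription factors known as Polycomb targets, markers of endoderm, mesoderm, neural cells, trophoblast and fibroblasts, Polycomb and H3K27 demethylase genes, m6A factors, immediate early genes, 2-cell stage genes, imprinted genes, splicing factors, cell cycle genes, ribosomal protein genes, nuclear genes for mitochondrial ribosomes and respiration, replication-dependent histones, and olfactory receptors. All members were matched to the table except in the 2-cell list (17 of 21) and the imprinted list (28 of 35). Each list was compared with all other protein-coding genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 18 lists.

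The rule for named regions was also fixed in advance. It took, per antibody, the 10 best ranked regions called in all 4 libraries, the 5 best called in both control and no CKO library, and the 5 best called in both CKO and no control library. It also took the 10 best called in all 4 control libraries of both antibodies, up to 6 members of each gene list with a replicated control region, and Mettl3 and Mettl14. One gene that the rule selects is not reported here. Ranking by score, and otherwise by width, had been planned. Neither varied, so the order of the peaks in each list was used, a choice made after seeing the data. That order ran in parallel between METTL14 lists over the shared peaks (Spearman's rho 0.70 to 0.77) and between METTL3 lists (0.95 to 0.97). These correlations are across peaks, which are not independent replicates.

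Alternatives fixed in advance were chromosomes 1 to 19 and X only, a 50% reciprocal overlap, peaks widened by 500 bp, windows of 1 kb and 5 kb, peaks of either library of a group, covered length, chance regions at drawn gene boundaries, a background without 3 large gene families, a replicate block, and each library left out in turn. A stricter score threshold was not run because the score did not vary. Added after seeing the data were lists shortened to the first peaks in file order (1439 for METTL14 and 242 for METTL3), lists without chromosome 8, lists without sites called by both antibodies, assignment to gene bodies with 2 kb on each side, and assignment to the nearest gene.

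The functions were tested on simulated data. A simulated share of 40% shared regions was recovered as 40%, where chance reached at most 0.2%. None of 20 unrelated pairs of lists had p below 0.05. That outcome was nearly fixed in advance, because narrow regions placed evenly over the genome almost never overlap. The simulation did not imitate the clustering of real peaks, so it does not give a false positive rate for them. In simulated gene sets over 21900 genes, 20 of 20 enriched lists were found and 1 unchanged list was called. Overlaps and Jaccard indices were equal to those of bedtools 2.31.1. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.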

Results

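METTL3 and METTL14 form the nuclear complex that writes N6-methyladenosine (m6A) on RNA, with METTL3 as the catalytic subunit. The genomic sites of both proteins were mapped by CUT&RUN in mouse embryonic stem cells (ESCs) grown with LIF and inhibitors of GSK3 and MEK. METTL14 was profiled in Mettl3 control and Mettl3 CKO cells, which addresses how far METTL14 sites depend on Mettl3. METTL3 was profiled in Mettl14 control and Mettl14 CKO cells for the reciprocal question. Each of the 4 groups had 2 libraries. The METTL14 lists held 3129 and 3546 peaks in the controls and 3922 and 1439 in the Mettl3 CKO libraries. The METTL3 lists were far shorter, with 353 and 341 peaks in the controls and 242 and 344 in the Mettl14 CKO libraries. The sequencing depth behind these lists is unknown. At the Mettl3 gene (chromosome 14: 52294841 to 52308741) and within 2 kb of it no library had a peak. At the Mettl14 gene (chromosome 3: 123368295 to 123385990) there was 1 METTL14 peak, in Mettl3 CKO replicate 1. Peak lists do not show whether either gene was lost, so they do not check the genotype labels.

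**Figure D1:**
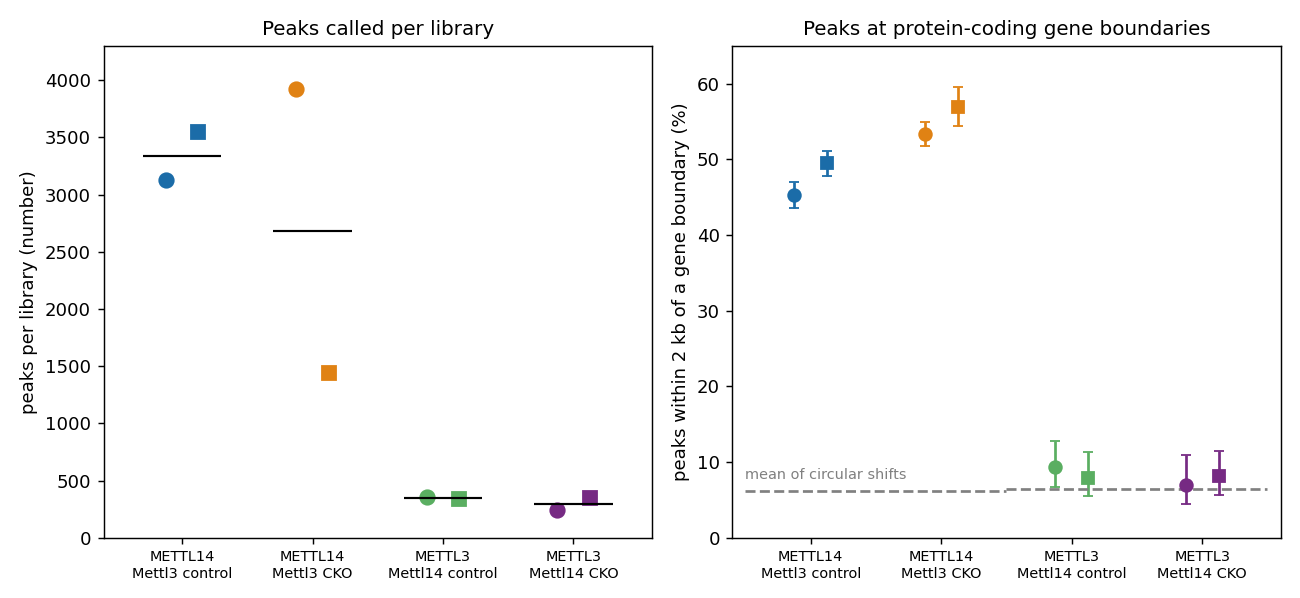
Peaks per library (left) and the percentage of peaks within 2 kb of a protein-coding gene boundary (right) in the 4 groups. Circles are replicate 1 and squares replicate 2, black lines are group means, error bars are 95% Wilson intervals, and dashed lines are the mean of circular shifts of the replicated control regions; METTL14 lists have 45.3% to 57.0% of peaks at gene boundaries, and METTL3 lists 7.02% to 9.35%.

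In control cells METTL14 regions lay at gene boundaries more often than chance placed them there. Of 1074 regions called in both control libraries, 579 (53.9%, 95% interval 50.9% to 56.9%) lay within 2 kb of a protein-coding gene boundary. Circular shifts placed 6.23% there on average (two-sided circular-shift permutation p = 0.0002, the smallest the shifts can give). These regions marked 700 genes, and 316 regions (29.4%, 26.8% to 32.2%) lay neither in nor near a protein-coding gene. The 10 best ranked regions called in all 4 METTL14 libraries were all away from gene boundaries, at distances of 29411 to 1035408 bp. They included chromosome 2: 98667081 to 98667243, chromosome 6: 103649150 to 103649300, inside Chl1, and chromosome 9: 35305369 to 35305518, and 6 of the 10 overlapped one of the 10 best ranked METTL3 regions. Among the lists, developmental transcription factors, known as Polycomb targets in ESCs, stood out. Their expression was not measured here. Of the 72 members 21 had a replicated region, against 3.11% of other genes (odds ratio 12.8, Fisher's exact p = 4.93e-15, adjusted p = 4.44e-14). In the single control libraries 39 and 41 of the 72 members had a peak. The best ranked members included Hoxd10, Hoxa7, Nkx6-1, Hoxd13 and Hoxa9. A member was counted for a region near either boundary, which need not be its own promoter. The Hoxd10 region (chromosome 2: 74682234 to 74682382) lay inside Hoxd11 as annotated (74679558 to 74687016). At Nkx6-1, a regulator of pancreatic and motor neuron fate, the region was at chromosome 5: 101665178 to 101665327. It lay outside the gene (101659184 to 101664711), beyond the boundary with the higher coordinate. Without strand, whether that boundary is the transcription start was not determined here. Olfactory receptor genes, not expected to be active in these cells, had no replicated region at any of 1110 members (adjusted p = 3.43e-15 by Fisher's exact test).

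Immediate early genes, which respond rapidly to growth signals, had regions at 4 of 19 members (odds ratio 8.12, Fisher's exact adjusted p = 0.0164). These were Egr1 (chromosome 18: 34860905 to 34861064), Fos (chromosome 12: 85473639 to 85473789), Jund (chromosome 8: 70698560 to 70698715) and Fosb (chromosome 7: 19310094 to 19310249). Neural and ectoderm markers had regions at 3 of 15 members (odds ratio 7.60, Fisher's exact adjusted p = 0.0500): Otx2, Pou3f2 and Zic2, all transcription factors of the early nervous system. Otx2 carried 3 separate regions. Both calls were close to the threshold. Both calls ended when the peaks of chromosome 8, which holds Jund, were removed. Genes of that chromosome stayed in the test as unmarked, so the immediate early count fell by construction and fewer other genes counted as marked. A background without those genes was not run. The adjusted p of Fisher's exact test was then 0.0563 for immediate early genes and 0.0547 for neural markers, leaving 1 list over-represented in place of 3. The odds ratios were then 6.14 (3 of 19) and 8.19 (3 of 15), and the unadjusted p was 0.0178 and 0.00911, against 0.00273 and 0.0111 with chromosome 8, so the neural call was lost through the adjustment over lists. The neural call also ended without the olfactory, vomeronasal and keratin-associated families in the background (Fisher's exact adjusted p = 0.0809), with an odds ratio of 7.05 for the same 3 of 15 members.

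The remaining lists did not pass in the replicated control regions. Ribosomal protein genes had regions at 7 of 84 members (adjusted p = 0.0646 by Fisher's exact test), among them Rpl21, Rpl4, Rpl7 and Rpl32. Nuclear genes for mitochondrial ribosomes and respiration had 11 of 170 (Fisher's exact adjusted p = 0.0747), including Uqcrh and Mrps28. Histone genes had 5 of 63 (Fisher's exact adjusted p = 0.130), all on chromosome 13 and from 2 regions: H2bc7, H2ac7 and H3c4 shared the region at 23575475 to 23575644, and H3c3 and H2bc3 the region at 23746384 to 23746552. Polycomb and H3K27 demethylase genes had 3 of 28 (Fisher's exact adjusted p = 0.133): Cbx8 and Bmi1, both members of Polycomb repressive complexes, and Phf1. Of the m6A factors, 2 of 23 had regions, the reader genes Hnrnpa2b1 and Igf2bp3. The imprinted neighbours Sgce and Peg10 shared 1 region (2 of 28 members). Single members had regions among endoderm (Foxa2, 1 of 20), mesoderm (Eomes, 1 of 14) and trophoblast markers (Gata3, 1 of 14), splicing factors (Snrpd2, 1 of 32) and cell cycle genes (Mcm4, 1 of 36). Pluripotency factors (0 of 25), fibroblast markers (0 of 15) and 2-cell stage genes (0 of 17) had none. Single libraries gave more calls: 9 lists passed in control replicate 1 alone and 7 in control replicate 2 alone.

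**Figure D2:**
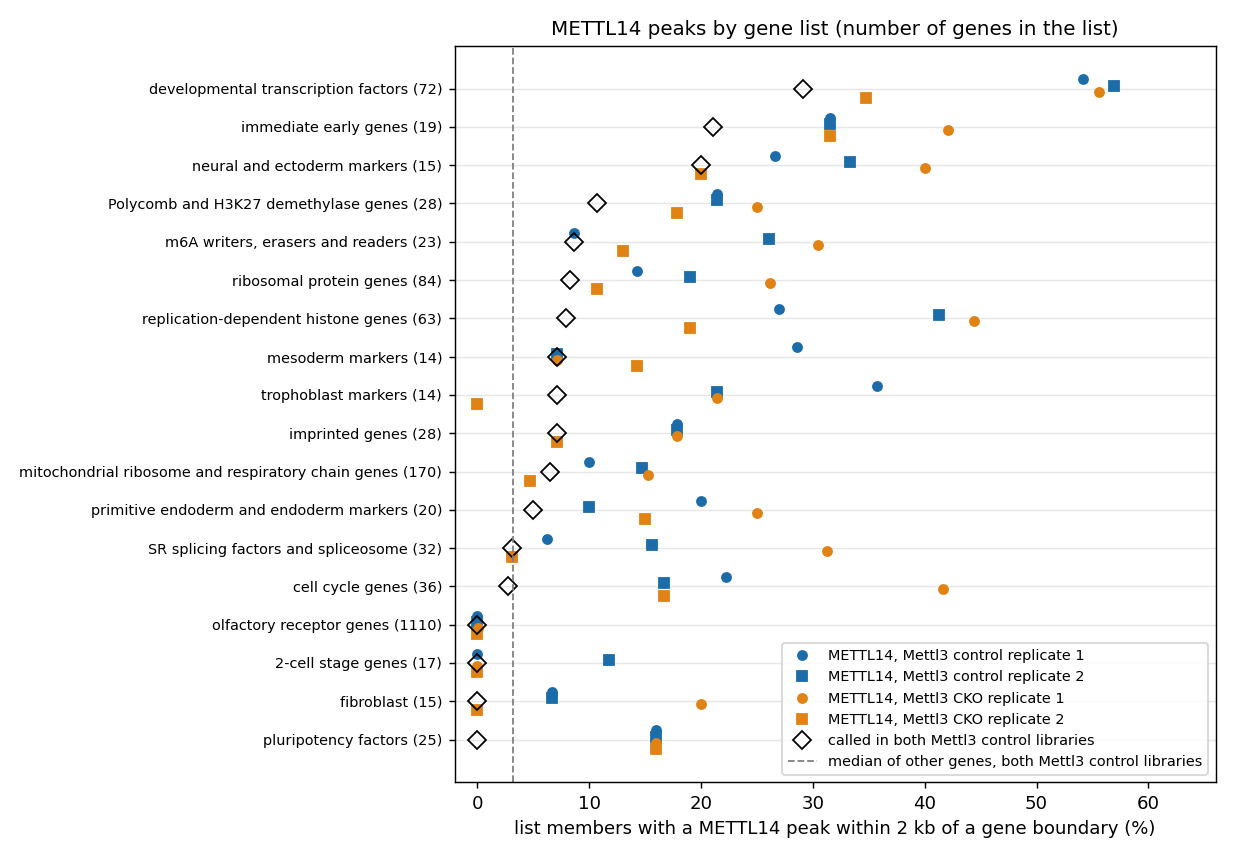
Percentage of the members of each gene list (vertical axis, list size in brackets) with a METTL14 peak within 2 kb of a gene boundary. Filled symbols are single libraries (developmental transcription factors reach 34.7% to 56.9%), diamonds are regions called in both Mettl3 control libraries, and the dashed line is the median share of genes outside a list for those regions.

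The 4 Hox clusters, which pattern the body axis and were singled out after their values were seen, carried dense METTL14 peaks. The clusters span 492097 bp. Control libraries had 51 and 73 peaks in them and Mettl3 CKO libraries 64 and 44, where circular shifts of the same lists gave means of 0.345 to 0.906 peaks (one-sided permutation p = 0.0001 in each of the 4 libraries, the smallest the shifts can give). Replicated regions numbered 29 in control and 25 in CKO cells. By cluster, the control count was 9 for Hoxa (chromosome 6: 52155367 to 52260880), 7 for Hoxb (chromosome 11: 96194316 to 96368254), 5 for Hoxc (chromosome 15: 102921131 to 103036856) and 8 for Hoxd (chromosome 2: 74668225 to 74765142). The CKO counts were 7, 6, 6 and 6. The replicated regions marked 18 of 39 Hox genes in control and 20 of 39 in CKO cells. No METTL3 library had a peak in a Hox cluster.

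**Figure D3:**
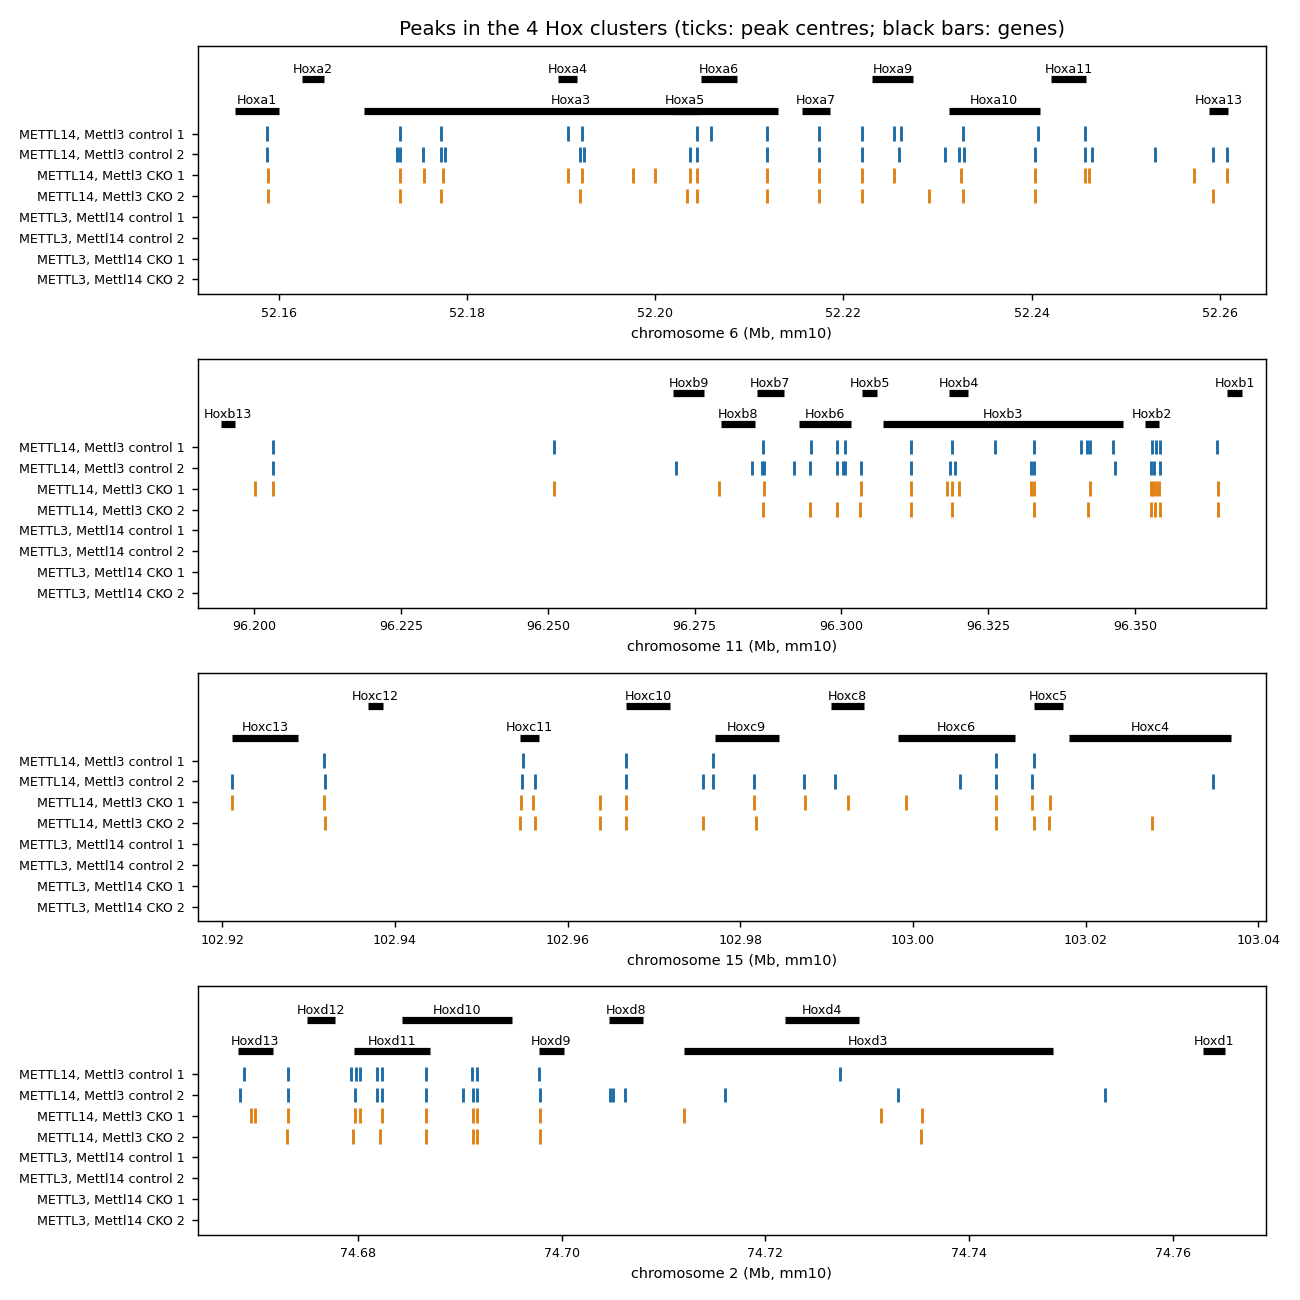
Map of the 4 Hox clusters with genes as black bars and the centre of each peak as a tick, 1 row per library (1 and 2 are replicates), horizontal axis in Mb of mm10. METTL14 peaks fall at many of the same sites in the 2 control and 2 Mettl3 CKO libraries, with 51, 73, 64 and 44 peaks, and the METTL3 rows are empty.

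In Mettl3 CKO cells METTL14 peaks were found at many of the same sites. Of the 1074 replicated control regions, 453 (42.2%, 39.3% to 45.2%) were overlapped by a replicated CKO region, and circular shifts gave 0.648% on average and 2.98% at most (one-sided permutation p = 0.0001, the smallest possible). A peak of at least 1 CKO library overlapped 77.4%, a peak of CKO replicate 1 alone 70.6%, and a peak of CKO replicate 2 alone 48.8%. With 1 control library in place of both the share was 17.1% without replicate 1 and 18.2% without replicate 2. The 856 replicated CKO regions lay at gene boundaries in 56.1% of cases (52.7% to 59.4%) and marked 577 genes. Of the 700 control genes 324 were also marked in CKO cells, where 18.4 would coincide if the gene sets were independent. Of the 21 developmental transcription factors marked in control cells, 14 had a replicated CKO region, Hoxa7, Hoxa9, Hoxd13 and Nkx6-1 among them. All 21 had a peak in at least 1 CKO library. The list had 18 of 72 members marked in CKO cells (odds ratio 12.7, Fisher's exact adjusted p = 2.87e-12). Of the immediate early genes Egr1, Fos and Fosb had a replicated CKO region, and of the neural markers Otx2 and Pou3f2. In replicated CKO regions 5 lists were over-represented by Fisher's exact test. Besides the developmental list these were immediate early genes (4 of 19, odds ratio 9.92, Fisher's exact adjusted p = 0.00809), Polycomb and H3K27 demethylase genes (4 of 28, odds ratio 6.20, adjusted p = 0.0224), histone genes (6 of 63, from 3 regions, odds ratio 3.92, adjusted p = 0.0224) and cell cycle genes (4 of 36, odds ratio 4.64, adjusted p = 0.0432). Neural markers did not pass (2 of 15, odds ratio 5.70, Fisher's exact adjusted p = 0.131), and olfactory receptor genes had 0 of 1110. A difference between control and CKO in any list was not tested.

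The number of METTL14 peaks did not separate control from CKO. It averaged 3338 ± 295 (SD, n = 2) in control and 2681 ± 1756 (SD, n = 2) in CKO cells, a log2 difference of -0.49 (exact permutation p = 1). Without CKO replicate 2 the difference was 0.24, and without CKO replicate 1 it was -1.21, so the sign rested on 1 short list. With all lists shortened to 1439 peaks, 41.3% of the peaks of CKO replicate 2 were found on average in another METTL14 list, against 42.0% to 44.0% for the other libraries. Libraries of the same group shared no more than libraries of different groups: the mean Jaccard index was 0.145 within and 0.149 between groups (difference -0.0038, exact permutation p = 0.667). At equal list length the difference turned to 0.00977 (exact permutation p = 0.333, the smallest that the 3 splits allow), and without CKO replicate 1 it was 0.00495.

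Over the 4 METTL14 libraries there were 8091 merged regions, of which 5720 were called in 1 library and 468 in all 4. Both control but no CKO library had 243 regions, and both CKO but no control library had 141, which makes 384. The other ways to pair the 4 libraries gave 391 and 494. At equal list length the control and CKO pairs had 121 and 124 regions of their own, 245 in all, and the other pairings 182 and 211. The 3 splits are too few for a test below 0.05. The best ranked region of both control libraries alone lay at chromosome 17: 39847582 to 39847735 in the 18S ribosomal RNA pseudogene Rn18s-rs5, and that of both CKO libraries alone at chromosome 17: 39843070 to 39843218, in the same neighbourhood. The others included sites within Sfi1 (chromosome 11: 3193398 to 3193599 and 3185307 to 3185579) and near an end of Tmem267 in controls. In CKO libraries they included mitochondrial DNA within ND4 and ND1, and the body of Tfap2a (chromosome 13: 40733758 to 40733968), a transcription factor of neural crest and epidermis. For the chromosome 17, Sfi1 and Tmem267 sites, regions called in all 8 libraries lay nearby. Examples are chromosome 17: 39843559 to 39843929, chromosome 11: 3199454 to 3199976 and chromosome 13: 119601878 to 119602251. Those 3 places therefore do not show by themselves a site gained or lost with Mettl3.

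METTL3 regions lay at gene boundaries less often than METTL14 regions, but the METTL3 lists were far shorter. The antibodies were not compared at equal list length, so the contrast cannot be separated from list length. The 80 regions called in all 8 libraries ranked on average at 4.33% of the METTL14 lists, and 5 lay at a gene boundary. METTL14 lists shortened to equal length, still longer than the METTL3 lists, had 48.4% of replicated control regions at boundaries. Of 121 regions called in both Mettl14 control libraries, 7 (5.79%, 2.83% to 11.5%) lay within 2 kb of a gene boundary, where circular shifts gave 6.47% on average (two-sided permutation p = 1). A further 90 regions (74.4%) lay neither in nor near a protein-coding gene. The regions marked 9 genes, listed after their values were seen: 4931408C20Rik, Brox, Lars2, LOC100504180, Gm51877, Elobl and the mitochondrial genes ND5, ND6 and CYTB. Fisher's exact test called 0 of the 18 gene lists, and 0 at an unadjusted p below 0.05. With 9 of 21900 protein-coding genes marked, an absence of calls was likely whatever the distribution. It is no evidence that METTL3 avoids the listed genes or differs from METTL14. Some of the regions gathered at few places, with 22 of the 121 on 1 unplaced contig of the assembly. Another 16 lay in the first 3.3 Mb of chromosome 9, and most lay elsewhere. The best ranked sites in all 4 METTL3 libraries were chromosome 2: 98666962 to 98667246, more than 1 Mb from the nearest gene boundary, chromosome 9: 35305305 to 35305589, in the lncRNA gene Gm33838, chromosome 6: 103649082 to 103649366, inside Chl1, the noncoding end of the mitochondrial genome (15478 to 15763) and chromosome 14: 19415734 to 19416018. Peaks of either control library were at gene boundaries in 9.25% of regions (two-sided permutation p = 0.0134 against circular shifts), without replicate 2 in 9.35% (p = 0.0390) and without replicate 1 in 7.92% (p = 0.327).

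In Mettl14 CKO cells most of the replicated METTL3 regions were found again, while most single METTL3 peaks were not shared between libraries. Of 871 merged regions over the 4 METTL3 libraries, 687 (78.9%) were called in 1 library and 91 in all 4. Of the 121 replicated control regions 90 (74.4%, 65.9% to 81.3%) were overlapped by a replicated CKO region, against 3.20% for circular shifts (one-sided permutation p = 0.0001, the smallest possible). With 1 control library in place of both the share was 28.7% without replicate 1 and 28.3% without replicate 2. Of the 121 replicated control regions 114 were also overlapped by a peak of at least 1 METTL14 library. The 74.4% therefore mostly describes sites called with both antibodies. Without such sites 7 replicated control regions were left, and 1 of them was overlapped in Mettl14 CKO cells. Of the 9 genes marked in controls 6 were among the 12 marked in CKO cells, which also held Relb and Slc30a4, named after their values were seen. Peak number averaged 347 ± 8.49 (SD, n = 2) in control and 293 ± 72.1 (SD, n = 2) in CKO cells (log2 difference -0.27, exact permutation p = 0.667). The difference was -0.01 without CKO replicate 1 and -0.52 without CKO replicate 2. The Jaccard index was 0.193 within and 0.187 between groups (difference 0.00599, exact permutation p = 0.333, the smallest possible), and without CKO replicate 2 the difference was -0.0330. Both control but no CKO library had 7 regions and both CKO but no control library 12, 19 in all, against 12 and 19 for the other pairings. Control-only regions included a pair between Tubb3 and Def8 (chromosome 8: 123427997 to 123428331 and 123431360 to 123431771), and CKO-only regions a site inside Zfp978 (chromosome 4: 147336927 to 147337298).

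Chromosome 8, singled out after its values were seen, held many METTL3 peaks. In the METTL3 lists 13.6% to 20.2% of peaks fell on chromosome 8, which makes up 4.95% of the mapped length of chromosomes 1 to 19 and X. The METTL14 lists had 4.52% to 4.96% there.

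**Figure D4:**
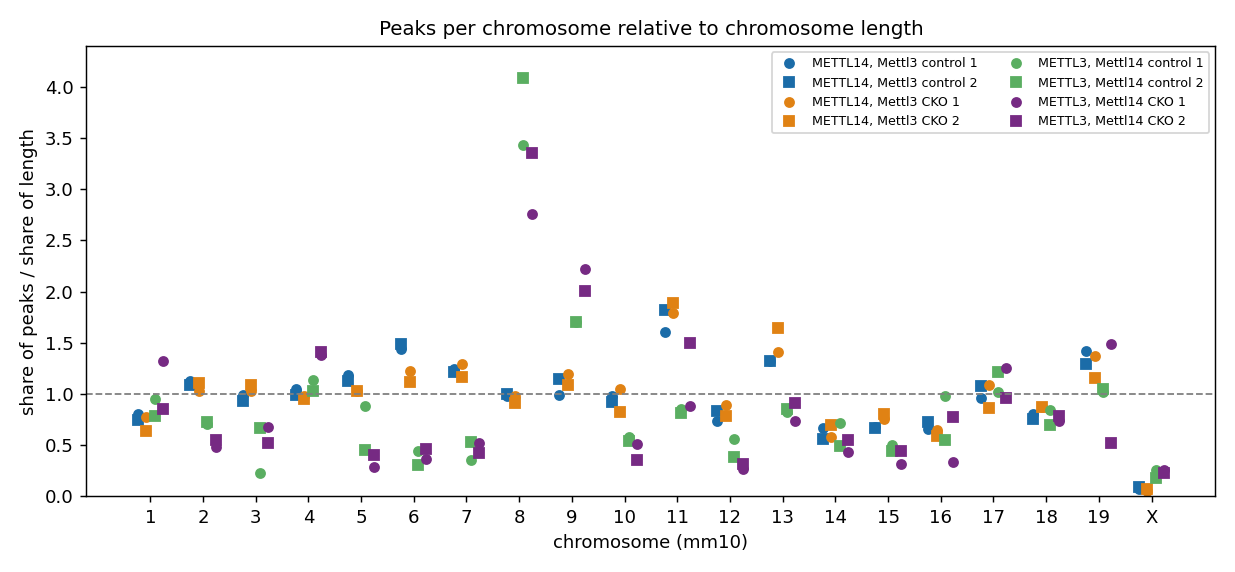
Share of each library's peaks on a chromosome divided by the chromosome's share of the mapped length (vertical axis), for chromosomes 1 to 19 and X, with 1 symbol per library and a dashed line at 1. The 4 METTL3 libraries reach 2.76 to 4.09 on chromosome 8, and the 4 METTL14 libraries 0.913 to 1.00.

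Most replicated METTL3 regions were also called with the METTL14 antibody. Overlap of calls does not tell joint binding of both proteins from pile-up whatever the antibody. Of the 121 replicated METTL3 control regions 95 (78.5%, 70.4% to 84.9%) were overlapped by a replicated METTL14 control region, against 3.97% for circular shifts (one-sided permutation p = 0.0001, the smallest possible). Any of the 4 METTL14 lists overlapped 114 of them (94.2%, 88.5% to 97.2%). In the other direction 158 of the 1074 METTL14 control regions (14.7%, 12.7% to 17.0%) met a METTL3 peak in any library. The best ranked regions of all 4 control libraries were again the site at 98666962 of chromosome 2 and those in Gm33838 and in Chl1. Of the 9 genes marked in METTL3 controls 8 were also marked in METTL14 controls. Without sites called by both antibodies, 7 replicated METTL3 control regions were left and 1 of them (14.3%) was overlapped in Mettl14 CKO cells. The METTL14 share overlapped in Mettl3 CKO cells was then 37.0%, and 61.8% of METTL14 control regions lay at gene boundaries. With 1 METTL3 control library in place of both, the share met by METTL14 fell to 32.3% without replicate 1 and 33.4% without replicate 2.

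**Figure D5:**
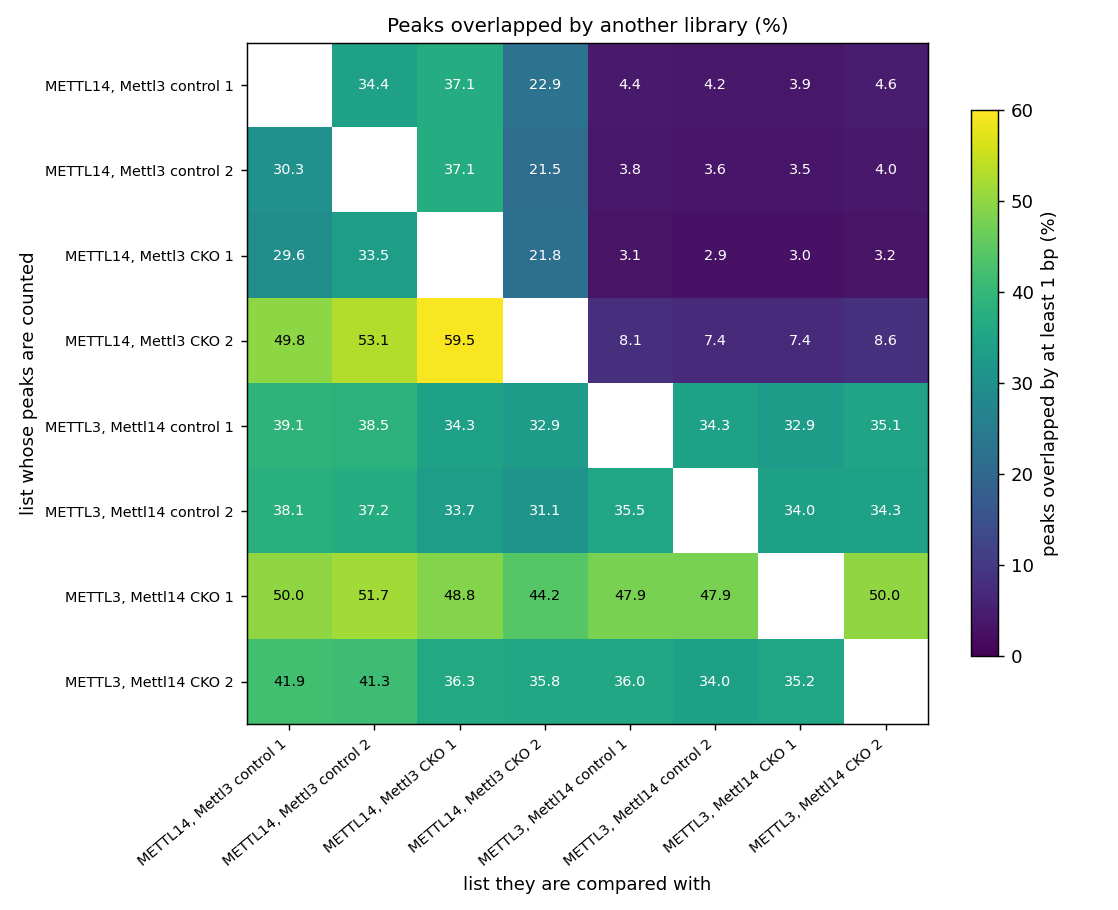
Percentage of the peaks of each list (rows) overlapped by at least 1 bp by each other list (columns), for the 8 libraries. METTL3 lists are overlapped by METTL14 lists about as often as by one another, and METTL14 lists are overlapped among themselves in 21.5% to 59.5% of peaks.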

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

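Shortened lists, the nearest gene, gene bodies, the removal of chromosome 8 and that of sites shared by both antibodies were chosen after the data were seen. The 11 results were recomputed under 115 alternatives, of which 102 kept their direction and side of the threshold or, for counts of gene lists, stayed within 1.5 times the count. The cause of the changes was not tested unless stated. The log2 difference in METTL14 peak number ran from -1.21 to 0.24 when single libraries were left out, and that of METTL3 from -0.52 to -0.01. The METTL14 Jaccard difference was 0.00977 with lists shortened to equal length, and -0.00873 to 0.00495 with single libraries left out; for METTL3 the latter range was -0.0330 to 0.0292. The number of METTL14 gene lists called, 3, was 2 without 3 gene families in the background, where the neural call was lost, and 4 with windows of 1 kb or 5 kb or lists of equal length. It was 9 with peaks of either control library, 7 with gene bodies and 2 kb on each side, and 1 without the peaks of chromosome 8. With 1 control library left out it was 7 to 9, where single-library peaks mark more genes by construction. The METTL3 share at gene boundaries moved from under to over the mean of the shifts, without differing from it, on chromosomes 1 to 19 and X (6.52%, permutation p = 0.996). It was above the shifts with peaks of either control library (9.25%, permutation p = 0.0134), and 7.92% (p = 0.327) to 9.35% (p = 0.0390) with 1 control library left out. Shares overlapped in CKO cells stayed above chance with single libraries left out, at 17.1% to 70.6% for METTL14 and 28.3% to 85.1% for METTL3. The lower ends come from single control libraries, which hold unreplicated peaks. Stricter score thresholds were not run.

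Libraries of the groups compared share only a replicate number. The correlation of presence between same-numbered libraries, around the group means, was 0.00715 for METTL14 and -0.0145 for METTL3 regions. With a replicate block the log2 differences in peak number were -0.49 and -0.27 (exact sign flip p = 1 each, smallest possible 0.5), and the shares overlapped between same-numbered libraries were 29.3% for METTL14 and 33.6% for METTL3. The block changed no call. Unknown depth limits comparisons of peak number, and 2 libraries per group cannot give p below 0.33.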

Other observations

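Several tests here were chosen after the result was seen: those on developmental genes and on the spread along chromosome 8, and chromosome 8 itself was noticed in the data. A further test, of whether the short METTL14 list of Mettl3 CKO replicate 2 held the same sites as the others, was written before its result and met its prediction; it was left out of the weighed patterns after that result was known, when chromosome 8 was taken up, and its value (41.3% against 42.0% to 44.0%) stands with the METTL14 comparison.

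In single METTL14 libraries further gene groups passed. Replication-dependent histone genes, which package newly made DNA, had a peak at 12 to 28 of 63 members (odds ratios 4.87 to 7.41) and were called in 4 of 4 libraries by Fisher's exact test with Benjamini-Hochberg adjustment. Neighbouring histone genes shared peaks, with 9 to 17 distinct peaks behind these counts, so the test, which takes genes as independent, overstates the evidence. Ribosomal protein genes had 9 to 22 of 84 members (odds ratios 2.19 to 3.08) and were also called in 4 of 4 libraries, as were immediate early genes (6 to 8 of 19) and neural markers (3 to 6 of 15). Cell cycle genes were called in 3 of 4 libraries, with 6 to 15 of 36 members; Cdkn2a and Mcm4, named after their values were seen, had a peak in all 4. Polycomb and H3K27 demethylase genes were called in 3 of 4 libraries (5 to 7 of 28), and Bmi1, Cbx8 and Phc1, also named after their values were seen, had a peak in all 4.

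Pluripotency factors had a peak at 4 of 25 members in each METTL14 library, but at different members. Klf2 and Tdgf1 had one in 3 libraries, Sox2 and Tbx3 in 2, and Pou5f1 and Nanog in 1 each, all named after their values were seen. The list was called in 1 of 4 libraries, Mettl3 CKO replicate 2. METTL14 regions of both CKO but no control library lay at gene boundaries in 64.5% of cases (56.4% to 72.0%, 141 regions), those of both control but no CKO library in 53.9% (47.6% to 60.1%, 243 regions), those of all 4 libraries in 50.9% (46.3% to 55.4%, 468 regions), and those of 1 library in 44.1% (42.8% to 45.4%, 5720 regions). Over all 8 libraries 80 regions were called in every list, and 5 of them lay at a gene boundary.

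For METTL14 at developmental transcription factor genes, a technical explanation is that peaks mark open chromatin at active promoters. The developmental list was marked more often than 7 lists taken as active genes, pooled (21 of 72 against 29 of 429, odds ratio 5.68, Fisher's exact p = 3.39e-07). Immediate early genes, one of these lists, were marked at 4 of 19 members (odds ratio of the developmental list over it 1.54, Fisher's exact p = 0.574). The other lists were marked at 0 of 25 (pluripotency) to 7 of 84 members (ribosomal protein genes). Whether immediate early genes were active in these cells, grown with a MEK inhibitor, is unknown here. That list therefore cannot decide, and this explanation stays open. The pool held pluripotency, cell cycle, splicing, ribosomal protein, mitochondrial, histone and immediate early genes, whose activity was not measured here; the first 4 of these lists alone, compared first, gave an odds ratio of 7.69. Neighbouring Hox genes counted several times were argued against as the whole cause, because 13 of 57 members outside the Hox clusters were marked (odds ratio 9.33, Fisher's exact p = 1.64e-08). That METTL14 is held at Polycomb target genes remains a hypothesis: the sequence composition of their CpG-rich promoters and the openness of chromatin in these cells were not analysed here, and the Mettl3 status of the cells does not separate these explanations.

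For METTL3 regions shared with METTL14, a candidate explanation is pile-up at sites away from genes whatever the antibody, such as repeats collapsed in the assembly. The shared regions lay at gene boundaries in 5.26% of cases (5 of 95), within the range of circular shifts (2.11% to 12.6%), but this decides nothing: with 7 METTL3 regions at boundaries in all, the share could not have passed that range. That most shared regions are gene sites of METTL14 is argued against by the same count, since 90 of the 95 lay away from gene boundaries; the odds ratio for METTL14 regions at boundaries against others to meet a METTL3 region (0.0392, 5 of 579 against 90 of 495) follows from that count and adds no evidence. Mappability and a library without specific antibody, which would test pile-up directly, were not analysed here, so pile-up and joint binding of both proteins at such sites both stay open.

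For METTL3 peaks on chromosome 8, the 3 fullest bins of 10 Mb held 34.4% (28.0% to 41.4%) of 189 single-library regions, which were spread over 13 bins. Those 3 bins therefore did not hold most of these regions. The criterion was set after the result, regions of 2 or more libraries were left out, and an even spread was not the reference. Local clustering was thus not excluded. Of the 189 single-library regions 6.35% lay at a gene boundary, within the range of circular shifts (2.65% to 9.52%), so they showed no excess there. Gene bodies farther than 2 kb from a boundary were not covered, so genes of chromosome 8 were not excluded as targets. Regions called in 1 METTL3 library lay on chromosome 8 more often (189 of 687) than regions called in 2 or more (13 of 184, odds ratio 4.99, Fisher's exact p = 2.72e-10), which is consistent with raised background along the whole chromosome. METTL14 regions showed no such excess (270 of 5720 against 119 of 2371, odds ratio 0.938). An extra copy of chromosome 8 in the Mettl14 control and CKO lines, a gain known from cultured mouse ESCs, may account for this and stays a hypothesis, since copy number was not measured and antibody and line changed together.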
